A study of Mus musculus with 8 samples.

How the data were processed

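RNA was measured in macrophages sorted from the hearts of wild-type C57BL/6 mice, 8 weeks of age, 3 days after myocardial infarction. Per the labels, cells with a high and a low level of the surface antigen Ly6C (Ly6Chi and Ly6Clo) were sorted apart and cultured for 24 hours with or without interleukin 21 (IL-21, 100 ng/mL). The 8 libraries form 4 groups of 2, and the replicate numbers come from the sample titles. Libraries were made with a QuantSeq 3' kit that reads the 3' end of each messenger RNA and with its module for unique molecular identifiers, and were read as 75-base single ends, per the labels' protocols.

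The deposited values are expected counts (estimated counts that need not be whole) per Ensembl gene, and the file headers call them raw. Of the genes above 0 in a library, 53.3 to 59.7% had a value that was not whole, at a tolerance of 0.001. The genome build mm10 and DESeq2 are named without a version, per the submitters' processing notes. The aligner, the counting program, the annotation release, and whether identifiers and strand were used are not given in the sources used here. Intervals and limits based on counts cover counting error only, and if the identifiers were not used, the counts include amplified copies of a molecule. Sharing of a read among the genes it matches would give such fractions and would divide the reads of near-identical genes between them. Each of the 8 tables holds 53342 genes, and total deposited counts were 224330 to 483593 per library.

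The design fixed before the data were examined assumed whole counts, so values were rounded to whole numbers first. Identifiers were matched to symbols and coordinates of the GENCODE M21 annotation of GRCm38 (mm10), and 53237 of 53342 identifiers matched. Genes were kept by edgeR's filterByExpr over the 4 groups (minimum count 10, minimum total 15), which left 5256 genes. Counts were normalised by TMM and fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in one model with 4 group means, and contrasts were tested with the robust quasi-likelihood F test. The fit had 4 residual degrees of freedom, a median of 10.6 prior degrees of freedom and a common biological coefficient of variation of 0.201. Adjusted p values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. CPM, counts scaled by library size, use the TMM-scaled totals of the genes kept, and group values are means with the standard deviation (SD). Fold changes are given with their standard error (SE).

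The contrasts were the IL-21 effect in each subset, its average over both, the difference between the subsets' IL-21 effects, and Ly6Clo against Ly6Chi without IL-21, with IL-21 and averaged. Before the data were examined, 27 gene lists were written from textbook knowledge, and the 16 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01. Adjustment was over the 16 lists within a comparison. Every list was also tested with an estimated correlation and with fry, and members were adjusted over the list alone as well.

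Named genes followed a rule fixed before the data were examined. For the IL-21 effect in each subset and the subset difference without IL-21, these are up to 10 called genes per direction by size of the log2 fold change, with a mean of at least 10 counts and no overlap between the groups. For the remaining contrasts the number is up to 5 per direction. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing. Up to 4 members of each list with the smallest p are named too, as are Il21r, Il2rg, Stat3, Socs3, Ly6c2, Ccr2, Arg1, Mmp9, Mmp12 and Il1b. Tmem8, Fgl2 and Dab2 in the averaged IL-21 effect fall outside the rule and were named after their values were seen. Mmp9 had 23 counts over all 8 libraries and was not tested.

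The fit was tested on simulated counts for the IL-21 contrast in Ly6Clo, with 5256 genes and 10 simulations. It called 79.3% of genes changed 4-fold, 19.2% of genes changed 2-fold and 0.16% of unchanged genes. In counts these were 793, 192 and 81 calls, so the share of false calls was above the 0.05 aimed at. Unlike the real libraries, the simulated ones held no difference shared by replicate number, so these rates need not hold for the real fit. Of the genes changed 4-fold, it called 92.5% of those above and 67.3% of those below the median expression. A list of 18 genes moved 1.5-fold was called in 10 of 10 simulations with the preset correlation and in 2 of 10 with an estimated one, and 0 of 150 unchanged lists were called by either. Genes were simulated independently of each other, so this does not show how often the preset correlation calls an unchanged list of correlated genes. For the IL-21 effect in Ly6Chi the estimated correlation was 0.71 for interferon-stimulated genes, 0.40 for ribosomal proteins and -0.045 for STAT3-linked genes. With the replicate number as a block these were 0.44, 0.12 and -0.043, so part of the first 2 came with the difference between the numbers. For STAT3-linked genes the camera p rose from 1.92e-06 to 0.00672 although the estimate was below the preset value. A call lost with an estimated correlation therefore need not come from correlated members.

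The last 500 bases of the transcripts of 79 named genes were compared with all other transcripts by blastn 2.17.0, at a match of at least 75 bases and 97% identity. For 9 genes a match held over 10% as many counts as the gene itself, and their values are reported as uncertain. Since the use of strand is not known, a gene that overlaps another one on the opposite strand cannot be separated from it either.

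Alternatives were the DESeq2 1.42.0 Wald test, RLE factors, limma-voom, no filter on low counts, a mean count of at least 20, a fit of only the libraries compared, the replicate number as a block, and each library left out in turn. Where leaving out a library leaves a group with 1 sample, that sample is assumed to vary like the other groups. That group then holds only 1 replicate number, so a difference between the numbers enters the contrast. Unrounded values and protein-coding genes only were added after the data were seen. Macrophages of mice lacking the IL-21 receptor, which the series title names, were not analysed here, nor were mitochondrially encoded genes.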

Results

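The libraries measured messenger RNA in macrophages of the infarcted mouse heart, kept in culture for 24 hours with or without IL-21, a cytokine made mainly by activated T cells. Macrophages were sorted 3 days after infarction into a Ly6Chi subset, which carries much of the surface antigen Ly6C, and a Ly6Clo subset, which carries little. Each of the 4 combinations of subset and stimulation had 2 libraries. Deposited totals were 261205 and 284174 counts in Ly6Chi without IL-21, 287131 and 224330 in Ly6Chi with IL-21, 257385 and 483593 in Ly6Clo without IL-21, and 269064 and 444670 in Ly6Clo with IL-21. At these depths 3 counts correspond to 6.58 to 14.9 CPM (counts scaled by library size), so a low transcript could be missed in a single library. The labels do not say whether replicates came from separate mice or cultures. The p values of genes therefore measure only the spread between these samples, which may be technical. A camera p sets the members of a list against the other genes tested, so it does not measure that spread alone. Libraries of the same number also shared differences, with 431 genes apart between the numbers in an edgeR fit adjusted for group. The fits reported here leave that difference in the spread. With the replicate number as a block, which assumes pairs that the labels do not give, more genes passed in every comparison. A gene said not to pass below may pass with that block.

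The receptor through which IL-21 acts was readable in all 8 libraries. Il21r, which encodes its specific chain (ENSMUSG00000030745, chromosome 7, 125603429 to 125633570, plus strand), had 24 to 68 counts per library. Il2rg, the shared gamma chain (ENSMUSG00000031304, chromosome X, 101264378 to 101268255, minus strand), had 31 to 92. In Ly6Chi cells the Il21r level was 118 ± 27.5 CPM without and 223 ± 70.6 CPM with IL-21, and in Ly6Clo cells 93.7 ± 8.39 and 176 ± 11.5 CPM (SD, n = 2 each). The averaged log2 fold change of Il21r was 0.91 (SE 0.21), with an adjusted p of 0.176 by edgeR's quasi-likelihood test, so it did not pass. With the replicate number as a block it did (0.91, SE 0.19, edgeR adjusted p 0.00713).

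The first comparison asked which transcripts responded to IL-21 with the subsets averaged, over 4 stimulated and 4 unstimulated libraries. Arg1, which encodes arginase 1, an enzyme that breaks down arginine, rose 3.57-fold, from 555 ± 97.1 to 1986 ± 274 CPM (SD, n = 4). Socs3, a feedback inhibitor of cytokine receptors that is induced through STAT3, rose 6.84-fold, from 25.7 ± 16.3 to 157 ± 49.4 CPM. Il4ra, the alpha chain of the interleukin 4 and interleukin 13 receptors, rose 4.07-fold, from 113 ± 49.4 to 471 ± 113 CPM. Ppbp, a chemokine gene best known from platelets, rose 3.69-fold, and Tgfbi, which encodes an extracellular matrix protein induced by TGF-beta, rose 2.02-fold. Cd38, an enzyme that consumes NAD, rose 3.24-fold. Tmem8, a membrane protein, Fgl2, a fibrinogen-like protein, and Dab2, an adaptor of endocytosis, rose 3.23-fold, 2.04-fold and 1.83-fold. These last 3 were named after their values were seen.

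These 9 of 5256 genes were all that passed in the averaged comparison, and each of them was higher in all 4 stimulated than in all 4 unstimulated libraries. With the replicate number as a block all 9 passed too, among 60 genes. The Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was 7.2e-05 for Arg1, 0.00062 for Socs3, 0.00133 for Tmem8, 0.00822 for Ppbp, 0.0105 for Tgfbi, 0.0186 for Cd38 and Il4ra, 0.0388 for Fgl2 and 0.0444 for Dab2. The log2 fold changes were 1.84 (SE 0.16) for Arg1, 2.77 (SE 0.31) for Socs3, 2.03 (SE 0.29) for Il4ra, 1.88 (SE 0.27) for Ppbp, 1.01 (SE 0.15) for Tgfbi, 1.70 (SE 0.28) for Cd38, 1.69 (SE 0.21) for Tmem8, 1.03 (SE 0.18) for Fgl2 and 0.87 (SE 0.16) for Dab2. Among libraries numbered 1 the log2 fold change was 1.94 for Arg1, 2.87 for Socs3 and 2.28 for Il4ra, and among those numbered 2 it was 1.73, 2.02 and 1.83. Arg1 (ENSMUSG00000019987) lies on chromosome 10 at 24915221 to 24927484, Socs3 (ENSMUSG00000053113) on chromosome 11 at 117966079 to 117970047, both on the minus strand, and Il4ra (ENSMUSG00000030748) on the plus strand of chromosome 7 at 125552120 to 125579474, next to Il21r. In this fit 0 genes fell past the threshold, and 5 of the 35 called without a filter on low counts were lower. The lowest p values in that direction belonged to Serpinb6b (log2 fold change -2.73, SE 0.61), Dio2 (-2.27, SE 0.52), Fscn1 (-2.35, SE 0.55), Rgs1 (-0.96, SE 0.24) and Tubgcp4 (-0.97, SE 0.25), with adjusted p values of 0.158 to 0.276 by the same edgeR test. Leaving out the Ly6Chi library without IL-21 numbered 2 left 5 of the 9 calls, and without the Ly6Clo library with IL-21 numbered 2 there were 15, which included all 9. Of the 8 fits with 1 library left out, 3 kept the call of Fgl2 and 2 that of Dab2, against 8 for Arg1, Socs3, Tmem8 and Ppbp. Part of the 3' end of Cd38 matches a 79-base stretch of other genes such as Sod2, so its counts are uncertain.

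**Figure D1:**
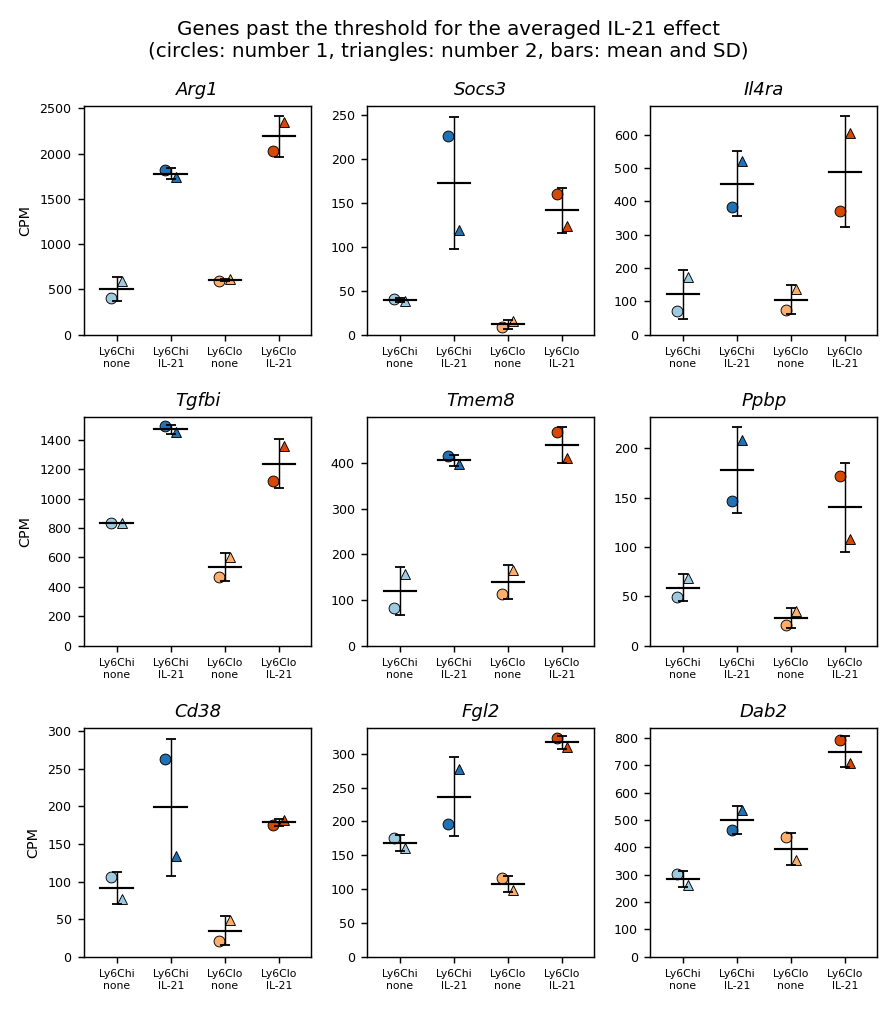
Each panel plots 1 of the 9 genes that rose in the averaged IL-21 comparison, with CPM on the vertical axis and the 4 groups on the horizontal axis, circles for libraries numbered 1, triangles for those numbered 2, and bars for the mean and SD (n = 2). For Arg1 the stimulated libraries lie between 1738 and 2354 CPM and the unstimulated ones between 410 and 617 CPM.

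Within the Ly6Chi subset, 1 gene, Arg1, passed. With the replicate number as a block 14 did, 13 of them higher, and these include Tmem8, Socs3, Ppbp and Nxpe5. The values that follow are from the fit without that block. The Arg1 level was 502 ± 131 CPM without and 1780 ± 59.8 CPM with IL-21 (SD, n = 2 each), a log2 fold change of 1.82 (SE 0.23) with an adjusted p of 0.00694 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold change was 2.13 among libraries numbered 1 and 1.54 among those numbered 2. Tmem8 (1.76, SE 0.30), Socs3 (2.14, SE 0.40), Ppbp (1.57, SE 0.38) and Nxpe5 (3.25, SE 0.71), which had higher means with IL-21, did not pass, at adjusted p values of 0.0947, 0.171, 0.79 and 0.79 by the same edgeR test. In the other direction the lowest p values belonged to Tubgcp4, a part of the gamma-tubulin complex that overlaps Zscan29 and Trp53bp1 on the opposite strand and is uncertain (-1.42, SE 0.38), the protease inhibitor Serpinb6b (-3.88, SE 1.10), Card19 (-1.06, SE 0.32), the transcription factor Mef2c (-1.53, SE 0.46) and the surface receptor Slamf9 (-2.31, SE 0.70), and none of these 5 passed. At an unadjusted p under 0.05 there were 185 genes, fewer than 0.05 of the 5256 tested, and 345 with the replicate number as a block. The Arg1 call ended without the first library with IL-21 (log2 fold change 1.80, edgeR adjusted p 0.0535) and without the first library without it (1.60, edgeR adjusted p 0.174).

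Within the Ly6Clo subset, 7 genes rose and 0 fell past the threshold. Arg1 went from 607 ± 13.3 to 2192 ± 228 CPM and Socs3 from 11.8 ± 4.99 to 142 ± 25.9 CPM (SD, n = 2 each). Tgfbi went from 533 ± 96.4 to 1237 ± 167 CPM, Fgl2 from 108 ± 12.4 to 317 ± 9.37 CPM and Tmem8 from 138 ± 37.1 to 440 ± 39.7 CPM. Cd38 went from 34.5 ± 19.5 to 179 ± 4.59 CPM and Ppbp from 27.9 ± 10.2 to 140 ± 44.9 CPM. The log2 fold changes were 1.85 (SE 0.23) for Arg1, 3.41 (SE 0.46) for Socs3, 1.57 (SE 0.26) for Fgl2, 2.25 (SE 0.41) for Cd38, 2.20 (SE 0.40) for Ppbp, 1.63 (SE 0.28) for Tmem8 and 1.21 (SE 0.22) for Tgfbi. Adjusted p values from edgeR's quasi-likelihood test were 0.00486 for Arg1, 0.00714 for Socs3, 0.0415 for Fgl2 and 0.0491 for Cd38, Ppbp, Tmem8 and Tgfbi. Il4ra had a log2 fold change of 2.17 (SE 0.40) and an edgeR adjusted p of 0.157, which did not pass, while with the replicate number as a block it was 2.11e-07. Among genes lower with IL-21, none of which passed, the smallest p values belonged to Rpl10 (-1.0, SE 0.24), Gpatch4 (-1.47, SE 0.41), Fscn1, which bundles actin (-2.35, SE 0.67), Mtap, an enzyme of methionine salvage (-1.72, SE 0.50), and Lsp1 (-2.81, SE 0.84).

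Arg1 rose by about the same in each pair of Ly6Clo libraries, by 1.75 on the log2 scale among those numbered 1 and by 1.92 among those numbered 2, and for Socs3 these values were 3.46 and 2.55. The count of 7 was 3 with DESeq2, 4 with limma-voom, 3 with unrounded values and 2 with a mean count of at least 20. It was 16 with no filter on low counts, 29 with the replicate number as a block, and 0 when the Ly6Chi libraries were left out of the fit, where 171 genes had an unadjusted p under 0.05. It was 4, 4 and 3 without the first Ly6Clo library with IL-21, the first without it and the second with it, 4 without the second Ly6Chi library with IL-21, and 0 without the second Ly6Clo library without IL-21, where 322 genes had an unadjusted p under 0.05.

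The IL-21 effects in the subsets were then compared directly. By edgeR's quasi-likelihood test 0 genes passed for a difference, and DESeq2 and limma-voom also called 0. This does not show equal responses at this depth. At an unadjusted p under 0.05 there were 92 genes by edgeR, 21 by DESeq2 and 89 by limma-voom. The 92 are fewer than 0.05 of the 5256 genes tested, the share expected without any difference, so they are no sign of one. With the replicate number as a block edgeR had 215 such genes, also under that share. The difference in log2 fold change, Ly6Clo minus Ly6Chi, was 0.03 (SE 0.32) for Arg1 and 1.27 (SE 0.66) for Socs3. Its smallest p belonged to Rpl10, a ribosomal protein gene, at -1.87 (SE 0.34) with an edgeR adjusted p of 0.394, which did not pass. Gpatch4 (-2.31, SE 0.61), the actin-binding Cnn2 (-1.99, SE 0.60), the mannosidase Man1a (-2.20, SE 0.70) and Phf21a (-2.03, SE 0.66) followed on that side. Rab29, a small GTPase (1.62, SE 0.49), Zc3h12d (1.96, SE 0.60), Mefv, which encodes pyrin (1.98, SE 0.61), and the collagens Col3a1 (3.84, SE 1.21) and Col1a2 (3.59, SE 1.16) came first on the other. Without a filter on low counts, 1 gene passed, and of the 16 lists 0 passed by camera, with 0.474 as the lowest adjusted p. Across the 5256 genes, which are not independent replicates, the log2 fold changes of the subsets had a Pearson r of 0.233 and a Spearman rho of 0.174, and r was 0.379 over the 2924 genes with a mean count of at least 20. Over the 732 genes with a mean log2 CPM above 8, r was 0.613 and rho 0.392. All 7 genes called in either subset had the same sign in both.

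The list of STAT3-linked response genes, which IL-21 signalling through STAT3 would engage, rose in both subsets. In Ly6Chi 15 of its 18 tested members were higher with IL-21, at a camera adjusted p of 3.08e-05, and adjusted p = 0.108 with an estimated correlation. That estimate was -0.045, below the preset 0.01, so correlated members do not account for the higher p. In Ly6Clo 15 of 18 were higher, at a camera adjusted p of 1.09e-07, and adjusted p = 0.0526 with an estimated correlation. Averaged over the subsets the camera adjusted p was 2.83e-10, and adjusted p = 0.0302 with an estimated correlation. By fry the adjusted p was 0.00374 in Ly6Chi, 0.00364 in Ly6Clo and 0.00125 averaged. In each of these comparisons this was the 1 list that passed by fry, so the other lists given below as rising or falling with IL-21 did not. Over all genes, 2 members rose in the averaged comparison, Socs3 and Il4ra, and 5 rose when adjusted over the list alone, among them Il21r and Bcl3 (log2 fold change 0.87, SE 0.27). Within Ly6Chi, 0 passed over all genes and 2 adjusted over the list alone, Socs3 and Il4ra, and within Ly6Clo these counts were 1 and 2. Hif1a (0.84, SE 0.33) in Ly6Chi and Cebpb (0.69, SE 0.27) in Ly6Clo, a transcription factor of myeloid cells, did not pass. Of the 10 tested receptor, JAK and STAT genes 6 were higher in Ly6Clo with IL-21, at a camera adjusted p of 0.0468 and adjusted p = 0.335 with an estimated correlation, kept in 5 of the 8 fits with 1 library left out, while in Ly6Chi 4 of 10 were higher (camera adjusted p 0.611). These include Il21r (0.91, SE 0.30), which both lists hold, Stat3 (0.64, SE 0.26) and Stat5b (1.66, SE 0.58), and 0 members passed over all genes or adjusted over the list alone.

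**Figure D2:**
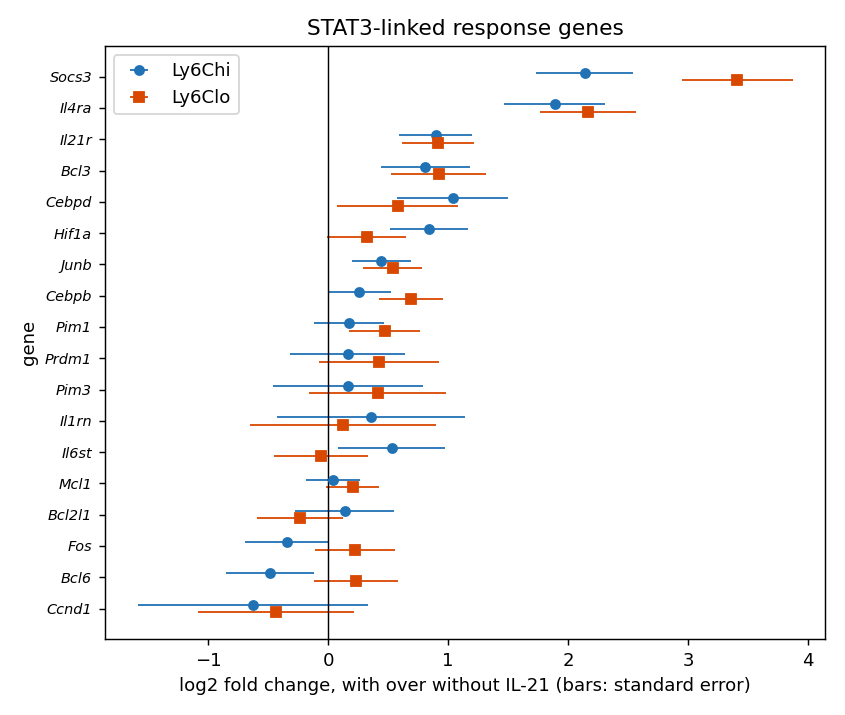
Log2 fold changes with over without IL-21 (horizontal axis) are plotted for the 18 tested STAT3-linked response genes (vertical axis), as circles for Ly6Chi and squares for Ly6Clo with bars for the standard error. Socs3 and Il4ra lie farthest to the right, at 2.14 and 1.89 in Ly6Chi and at 3.41 and 2.17 in Ly6Clo.

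Inflammatory cytokines and chemokines also rose as a list. In Ly6Clo 10 of the 15 tested members were higher with IL-21, at a camera adjusted p of 0.000434 and adjusted p = 0.417 with an estimated correlation. In Ly6Chi 11 of 15 were higher, at a camera adjusted p of 0.0477 and adjusted p = 0.829 with an estimated correlation. In these fits 0 members passed over all genes in either subset. With the replicate number as a block, members that passed included Ccl12 in each subset (edgeR adjusted p 0.000211 in Ly6Chi and 3.21e-06 in Ly6Clo). Cxcl3 (0.0174) and Cxcl16 (0.0209) passed that edgeR test in Ly6Clo. Adjusted over the list alone, 2 rose in Ly6Clo, the neutrophil-attracting chemokine gene Cxcl3 (1.57, SE 0.36) and Cxcl16 (0.88, SE 0.25), and 0 in Ly6Chi. For the averaged effect 4 rose when adjusted over the list alone, Cxcl3 (0.96, SE 0.23), the serum amyloid gene Saa3 (1.91, SE 0.47), the monocyte-attracting Ccl12 (2.48, SE 0.67) and Cxcl16 (0.53, SE 0.18). The Ccl12 level with IL-21 and without it was 75.3 and 16.4 CPM in the Ly6Chi libraries numbered 1, 283 and 45.8 CPM in those numbered 2, 104 and 16.6 CPM in the Ly6Clo libraries numbered 1, and 308 and 50.5 CPM in those numbered 2. Il1b, which encodes interleukin 1 beta, had 40 counts over all libraries and log2 fold changes of -0.14 (SE 0.95) in Ly6Chi and -2.07 (SE 1.44) in Ly6Clo. In Ly6Clo the list's camera adjusted p was 0.491 without the second library with IL-21.

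Markers of Ly6Clo and resident macrophages rose with IL-21 as well, with 13 of 15 tested members higher in Ly6Clo (camera adjusted p 0.00203, and adjusted p = 0.335 with an estimated correlation) and 12 of 15 in Ly6Chi (camera adjusted p 0.0477, and adjusted p = 0.829 with an estimated correlation). Pf4, a chemokine gene expressed by platelets and resident macrophages, had 1765 ± 128 CPM without and 3019 ± 310 CPM with IL-21 in Ly6Clo (SD, n = 2 each), and 1860 ± 103 and 3151 ± 564 CPM in Ly6Chi. It was the 1 member that rose when adjusted over the list alone, in each subset, while its averaged log2 fold change of 0.77 (SE 0.15) had an edgeR adjusted p of 0.0704 over all genes. With the replicate number as a block that edgeR adjusted p was 3.68e-05. The complement genes C1qb (0.44, SE 0.16) and C1qa (0.35, SE 0.15), whose averaged log2 fold changes were above 0, did not pass. In Ly6Clo the Ly6Chi monocyte markers were higher too, 10 of 13 (camera adjusted p 0.0262, and adjusted p = 0.345 with an estimated correlation), with F13a1 (1.23, SE 0.62), Chil3 (0.94, SE 0.65) and Ccr2 (0.78, SE 0.86) among them, while Ly6c2 was at -0.66 (SE 0.50). No member of that list passed over all genes or adjusted over the list alone. Wound-healing macrophage genes rose in Ly6Clo, with 10 of 17 higher, at a camera adjusted p of 0.0262 and adjusted p = 0.335 with an estimated correlation. The 2 members that passed, over all genes and adjusted over the list alone, were Arg1 and Tgfbi. In Ly6Chi that list did not pass, at a camera adjusted p of 0.611. Ribosomal protein genes fell slightly in Ly6Clo, with 26 of 29 lower and a median log2 fold change of -0.13 (camera adjusted p 0.0132, and adjusted p = 0.79 with an estimated correlation), and Rpl10 was the 1 member that passed adjusted over the list alone. Interferon-stimulated genes, with 29 tested members, did not pass in either subset, at camera adjusted p values of 0.611 and 0.393, nor did genes of glycolysis and the hypoxia response at 0.0826 and 0.552. The remaining 7 lists tested did not pass either, with camera adjusted p values of 0.309 or more. Of the 8 fits with 1 library left out, 2 kept the call of the inflammatory list in Ly6Chi and 0 that of the resident markers there.

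The subsets were compared next, first without IL-21. Ly6c2, which encodes the antigen used in the sort and so checks the sort rather than adding a finding, was at 479 ± 94.3 CPM in Ly6Chi and 60.1 ± 20.5 CPM in Ly6Clo (SD, n = 2 each). Cxcl3 was at 244 ± 43.2 CPM in Ly6Chi and 39.8 ± 15.1 CPM in Ly6Clo. These 2 genes passed, with log2 fold changes, Ly6Clo over Ly6Chi, of -2.92 (SE 0.41) and -2.52 (SE 0.35) and adjusted p values of 0.0284 and 0.0156 by edgeR's quasi-likelihood test. Among libraries numbered 1 and 2 the values were -3.39 and -2.36 for Ly6c2 and -2.97 and -1.94 for Cxcl3. Genes lower in Ly6Clo that did not pass included the orphan receptor Gpr141 (-1.80, SE 0.34), Mefv (-2.44, SE 0.46) and Ly6c1 (-3.40, SE 0.66), at edgeR adjusted p values of 0.136, 0.136 and 0.148. On the other side were Igf1, which encodes a growth factor (0.97, SE 0.21), the fatty acid binding protein gene Fabp7 (1.42, SE 0.32), Bcl2a1a, a relative of Bcl2 that inhibits cell death (1.35, SE 0.35), Serpinb6a (1.06, SE 0.28) and Bcl2a1b (0.92, SE 0.26), none of which passed. Arg1, at 0.27 (SE 0.23), did not pass, and neither did Mmp12, a metalloproteinase gene, at 1.12 (SE 0.92).

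Ly6c1 and Ly6c2 are 98.2 to 99% identical over matching stretches of their 3' ends, and Bcl2a1a and Bcl2a1b share such stretches with each other and with Bcl2a1d, so the division of counts within each family is uncertain. The count of 2 was 0 without the first or the second Ly6Clo library without IL-21, where 197 and 419 genes had an unadjusted p under 0.05. It was 1 without the second Ly6Chi library without IL-21 or either Ly6Chi library with it, and without the first Ly6Chi library without IL-21 it was 2 different genes. A mean count of at least 20 gave 1 and no filter 16.

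With IL-21, Ly6c2 was at 438 ± 93.4 CPM in Ly6Chi and 35.6 ± 33.3 CPM in Ly6Clo (SD, n = 2 each), a log2 fold change of -3.47 (SE 0.44) with an adjusted p of 0.0206 by edgeR's quasi-likelihood test, and it was the 1 gene past the threshold. Gpr141 (-1.98, SE 0.38), Ly6c1 (-3.36, SE 0.76) and Cxcl3 (-1.30, SE 0.30) did not pass, and Rpl10 was at -1.07 (SE 0.25), which did not pass either. Genes higher in Ly6Clo that did not pass were Pou1f1 (3.18, SE 0.64), whose 3' end matches repeats in other genes and is uncertain, Ckb, a creatine kinase gene (2.46, SE 0.52), Fabp4, a fatty acid binding protein gene (1.01, SE 0.22), Bcl2a1b (1.22, SE 0.27) and Wfdc17 (1.02, SE 0.26). The call of Ly6c2 ended without either Ly6Chi library with IL-21, at edgeR adjusted p values of 0.369 and 0.08, with only the 4 libraries compared in the fit (0.174) and with a mean count of at least 20 (0.059).

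Averaged over both conditions, 5 genes were lower and 5 higher in Ly6Clo. Chil3, which encodes a chitinase-like protein of monocytes and macrophages, was 4.48-fold lower (24.2 ± 16.3 against 106 ± 36 CPM, SD, n = 4 each), Cxcl3 3.77-fold lower and Gpr141 3.71-fold lower. Ly6c2 was 9.15-fold and Ly6c1, with a near-identical 3' end, 10.4-fold lower, which checks the sort rather than adding a finding. Igf1 was 1.86-fold higher (901 ± 172 against 481 ± 63.8 CPM), Fabp4 1.82-fold, Bcl2a1b 2.10-fold, Ckb 3.74-fold and Serpinb6a, a protease inhibitor gene, 2.14-fold. Adjusted p values by edgeR's quasi-likelihood test were 0.000837 for Ly6c2, 0.00154 for Cxcl3, 0.00431 for Gpr141, 0.0116 for Ly6c1 and 0.0226 for Igf1, and 0.036 or 0.037 for the other 5. All 10 genes were separated in the same direction in all libraries, 4 against 4. With the replicate number as a block all 10 passed too, among 132 genes. The edgeR adjusted p was then 1.02e-05 for Igf1, 0.000145 for Fabp4 and 0.000388 for Bcl2a1b. Serpinb6a overlaps Ripk1 and Nqo2 on the opposite strand and its counts are uncertain for that reason. Igf1 (ENSMUSG00000020053) lies on the plus strand of chromosome 10 at 87858265 to 87937042, Chil3 (ENSMUSG00000040809) on the minus strand of chromosome 3 at 106147554 to 106167564, and Cxcl3 (ENSMUSG00000029379) on the plus strand of chromosome 5 at 90786103 to 90789600. The count of 10 fell to 3 and 4 without the first and second Ly6Chi library with IL-21, to 6 and 4 without the first Ly6Clo library with and without IL-21, and rose to 22 without the second Ly6Clo library without IL-21. Of the 8 fits with 1 library left out, 8 kept Ly6c2, Cxcl3 and Gpr141, 7 Ly6c1, 3 Chil3 and Ckb, 2 Serpinb6a, 1 Igf1 and Bcl2a1b, and 0 Fabp4, and DESeq2 called 2 higher and 10 lower genes, 6 of them among these 10.

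**Figure D3:**
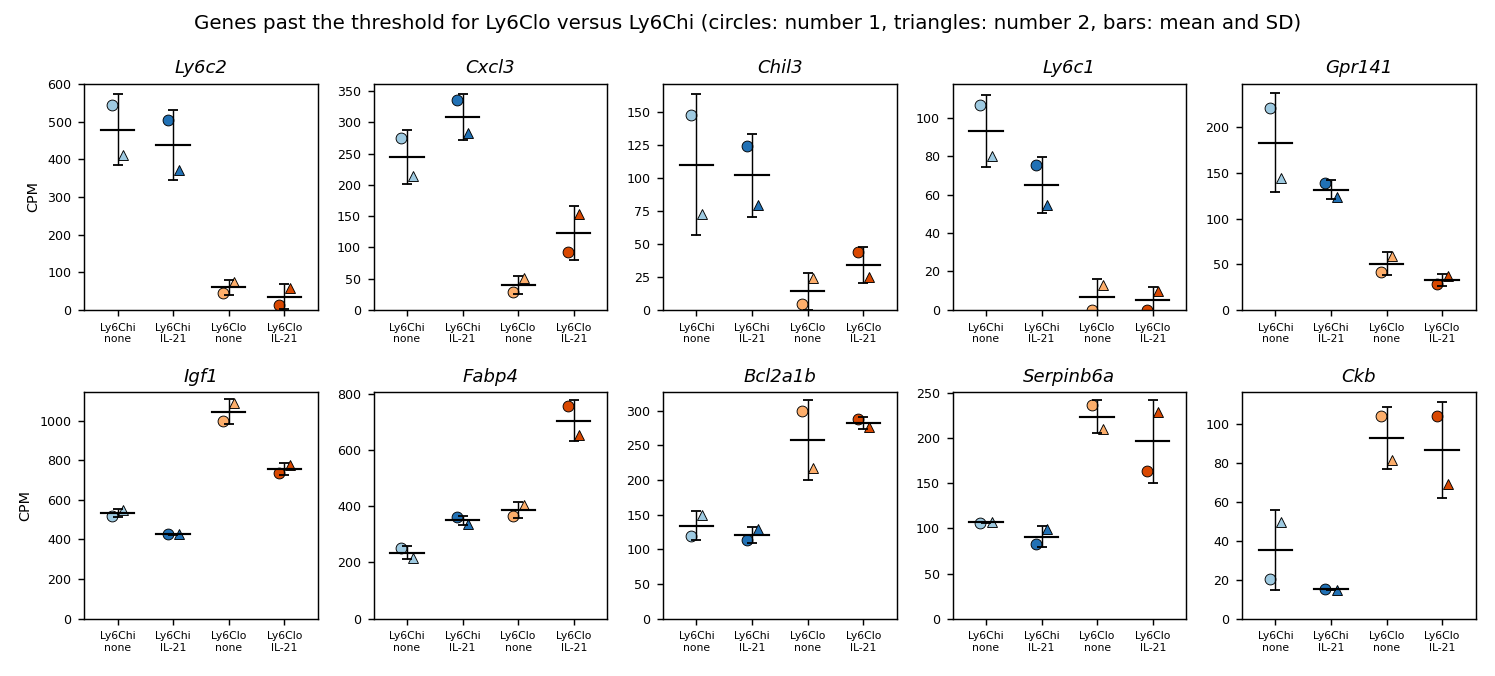
Each panel plots 1 of the 10 genes that differed between Ly6Clo and Ly6Chi in the averaged comparison, with CPM on the vertical axis and the 4 groups on the horizontal axis, circles for libraries numbered 1, triangles for those numbered 2, and bars for the mean and SD (n = 2). Igf1 lies between 735 and 1091 CPM in the 4 Ly6Clo libraries and between 425 and 549 CPM in the 4 Ly6Chi libraries.

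The Ly6Chi monocyte markers fell as a list in Ly6Clo without IL-21, with 12 of 13 tested members lower and a median log2 fold change of -1.40 (camera adjusted p 2.02e-12, and adjusted p = 0.0449 with an estimated correlation). The cells were sorted on Ly6C and the list holds markers of Ly6Chi cells, Ly6c2 among them, so its direction was largely set by the sort. With the replicate number as a block and an estimated correlation its camera adjusted p was 0.0789. Over all genes 1 member passed, Ly6c2, and adjusted over the list alone 3 did, Ly6c2, Chil3 (-2.67, SE 0.55) and the coagulation factor gene F10 (-1.41, SE 0.43), whose 3' end matches an 81-base stretch of Slc25a20 and is uncertain. Ccr2, the receptor through which monocytes are recruited, was at -0.27 (SE 0.91), with 1.49 among libraries numbered 1 and -1.87 among those numbered 2. Counts of 15 neutrophil markers, of which S100a8 and S100a9 are also in that list, were 523 and 371 in the Ly6Chi libraries and 304 and 295 in the Ly6Clo libraries without IL-21, not scaled for depth, and Mmp8 alone held 495, 337, 288 and 245 of these. With IL-21 the Ly6Chi list was again lower, 12 of 13 (camera adjusted p 3.75e-09, and adjusted p = 0.122 with an estimated correlation), and the averaged test had an adjusted p = 0.0289 with an estimated correlation. In the averaged test 5 members passed adjusted over the list alone, among them the matrix proteoglycan gene Vcan (-1.51, SE 0.36).

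Inflammatory cytokines and chemokines fell in Ly6Clo without IL-21, with 10 of 15 lower, at a camera adjusted p of 0.000144 and adjusted p = 0.441 with an estimated correlation. Over all genes 1 member passed, Cxcl3, and 2 adjusted over the list alone, Cxcl3 and Cxcl2 (-1.90, SE 0.53). Interferon-stimulated genes were lower in 27 of 29 tested members, at a camera adjusted p of 4.48e-06 and adjusted p = 0.441 with an estimated correlation, with 0 members past over all genes or adjusted over the list alone. Gbp5 (-1.92, SE 0.63), the RNA sensor gene Ddx58 (-0.75, SE 0.30) and Zbp1 (-0.72, SE 0.33) had the smallest p values there. Without the first Ly6Clo library without IL-21 the interferon list was at a camera adjusted p of 0.649. With IL-21 that list was again lower in 27 of 29, at a camera adjusted p of 0.00463 and adjusted p = 0.618 with an estimated correlation, and it turned without the first Ly6Clo library with IL-21 (camera adjusted p 0.567). Without IL-21, STAT3-linked genes were lower in 14 of 18 (camera adjusted p 0.00868, and adjusted p = 0.252 with an estimated correlation), with Socs3 at -1.60 (SE 0.57) and Cebpb at -0.93 (SE 0.27). That call was kept in 4 of the 8 fits with 1 library left out, and that of receptor, JAK and STAT genes, given next, in 5. By fry, 2 lists passed without IL-21, STAT3-linked genes (adjusted p 0.0153) and Ly6Chi monocyte markers (0.0493). Genes of class I antigen processing were lower in 12 of 13 (camera adjusted p 0.0112, and adjusted p = 0.473 with an estimated correlation), which turned without the first Ly6Clo library without IL-21 (camera adjusted p 0.935) and was at 0.678 without the second Ly6Chi library without it, and receptor, JAK and STAT genes in 8 of 10 (camera adjusted p 0.0367, and adjusted p = 0.349 with an estimated correlation).

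Resident macrophage markers were higher in Ly6Clo without IL-21 in 11 of 15 members, at a camera adjusted p of 0.0367 and adjusted p = 0.441 with an estimated correlation. Averaged over both conditions this list was at a camera adjusted p of 0.00179, and adjusted p = 0.252 with an estimated correlation. Members adjusted over the list alone then went both ways, with 7 higher, such as Gas6, a ligand of receptors that take up dying cells (1.25, SE 0.27), and C1qa (0.60, SE 0.15), and 2 lower, Maf (-0.67, SE 0.15) and Adgre1, which encodes the macrophage antigen F4/80 (-0.72, SE 0.17). All 6 tested class II genes were higher without IL-21 (camera adjusted p 0.0369, and adjusted p = 0.441 with an estimated correlation) and with it (camera adjusted p 0.00463, and adjusted p = 0.303 with an estimated correlation), where H2-Ab1 was at 0.73 (SE 0.24). Of the 8 fits with 1 library left out, 0 kept the call without IL-21. Ribosomal protein genes were higher in 25 of 29 without IL-21 (camera adjusted p 9.31e-05, and adjusted p = 0.441 with an estimated correlation), although Rpl11 (1.21, SE 0.35) and Rpl10 (0.81, SE 0.24) share their 3' ends with pseudogenes and are uncertain. Genes of lipid uptake, storage and efflux were higher in 12 of 15 with IL-21 (camera adjusted p 0.00232, and adjusted p = 0.144 with an estimated correlation), and in the averaged comparison 1 member passed over all genes, Fabp4, and 4 adjusted over the list alone, Fabp4, Lpl (0.60, SE 0.19), Apoe (0.52, SE 0.18) and Cd36 (0.52, SE 0.17). Wound-healing genes were higher in 11 of 17 with IL-21 (camera adjusted p 0.00671, and adjusted p = 0.178 with an estimated correlation), while 6 were lower.

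Markers of other cell types were read as counts, since few of them were tested. The 13 fibroblast markers had 20 and 53 counts in the Ly6Chi libraries without IL-21 and 9 and 21 with it, and 6 and 20 in the Ly6Clo libraries without IL-21 and 41 and 72 with it. Col3a1 and Col1a2 are among them, and without these 2 the counts were 9 and 28, 7 and 13, 2 and 11, and 24 and 37 in that order. The 13 endothelial markers, which include Ly6c1, had 21 to 119 counts per library and the 17 cardiomyocyte markers 30 to 68. B cell markers had 26 counts and markers of mast cells and basophils 7 counts over all 8 libraries. The 18 markers of T and NK cells had 150 to 407 counts per library, of which Il7r held 619 in the libraries numbered 1 and 1152 in those numbered 2 and the other 17 markers 18 and 40. The 13 dendritic cell markers, which include Fscn1, had 41 to 162.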

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

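The count of Rpl10 together with its copies was chosen only after the value of Rpl10 had been seen. Rpl10, which encodes a protein of the large ribosomal subunit, went in opposite directions with IL-21 in the subsets, from 190 ± 15.3 to 348 ± 8.02 CPM in Ly6Chi and from 331 ± 22.1 to 168 ± 39.2 CPM in Ly6Clo (SD, n = 2 each). The difference in log2 fold change was -1.87 (SE 0.34), with an edgeR quasi-likelihood adjusted p of 0.394 over all genes and 0.00218 adjusted over the ribosomal list alone. Its last 500 bases are 100% identical to those of the pseudogene Rpl10-ps3, which had 2292 counts against 599 for Rpl10, so a shift of reads between the copies could give this pattern without a change in Rpl10. With the replicate number as a block it was -1.90 (SE 0.30, edgeR adjusted p 0.00429). Rpl10-ps3 had 279 and 230 counts without and 296 and 176 with IL-21 in Ly6Chi. In Ly6Clo it had 289 and 381 without and 273 and 368 with it, none of these scaled for depth. Summed with 11 copies, the difference for Rpl10 was -0.36 (SE 0.33), but the copies hold 3.92 times the counts of Rpl10. A change of Rpl10 alone with flat copies predicts -0.36 too. No difference, which shared reads alone predict, is not far from it given the SE, so this sum cannot tell shared reads from a change in the gene.

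The collagen genes Col3a1 and Col1a2, which passed for the difference in response only when adjusted over the fibroblast list alone, of which they are the 2 tested members (edgeR quasi-likelihood adjusted p 0.00745 for each, and 1.0 over all genes), had differences in log2 fold change of 3.84 (SE 1.21) and 3.59 (SE 1.16), on 50 and 61 counts in all 8 libraries, and the counts of the other 11 fibroblast markers went from 9 and 28 to 7 and 13 with IL-21 in Ly6Chi and from 2 and 11 to 24 and 37 in Ly6Clo.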

How the results depend on the processing

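Unrounded values and protein-coding genes only were chosen only after the results had been seen, and the rest before. Counts of genes past an edgeR adjusted p of 0.05 moved as follows. IL-21 in Ly6Chi: 1, with no filter on low counts 8. IL-21 in Ly6Clo: 7, with DESeq2 3, limma-voom 4, no filter 16, a mean count of at least 20 2, unrounded values 3 and only the libraries compared 0 (171 at an unadjusted p under 0.05). Averaged: 9, with no filter 35. Difference between the IL-21 effects: 0, with no filter 1. Ly6Clo against Ly6Chi without IL-21: 2, with no filter 16 and a mean count of at least 20 1; with IL-21: 1, with no filter 22, a mean count of at least 20 0 (157) and only the libraries compared 0 (221); averaged: 10, with no filter 58. The correlation of the IL-21 effects was 0.233, and 0.379 with a mean count of at least 20. The cause was not tested.

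With the replicate number as a block (replicate block) the counts were 14, 29, 60, 1, 31, 41 and 132 in that order, which assumes pairs that the labels do not give. Of the 60, 8 were lower. Among the genes gained were Ccl12 and Il4ra in each subset, Cxcl3 and Cxcl16 in Ly6Clo, Il21r, Pf4 and Mrc1 in the averaged comparison, and Rpl10 for the difference. With that block and an estimated correlation, 0 lists passed in each of the 4 IL-21 comparisons and in the subset comparisons without and with IL-21, and 1 in the averaged one; STAT3-linked genes were at a camera adjusted p of 0.0661 (averaged IL-21 effect) and Ly6Chi markers at 0.0789 (subsets without IL-21). Deviations of libraries with the same number correlated at 0.234 to 0.412. Of the 34 splits of the 8 libraries into 4 and 4 counted for the averaged IL-21 effect, 2 gave as many genes, the real one (9) and the one that follows the numbers (346, the highest other), and the rest gave at most 1; for the subsets these were 2, with 13 and 219 (the splits use a fit with 1 covariate and no interaction, which calls 13 rather than 10). A share of 2 in 34 is over 0.05, but the split by number is 1 of the 2, so this count does not decide about chance. A split that calls that many genes points to a structure of the samples by number.

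With 1 library left out the counts ran from 0 to 3 (IL-21 in Ly6Chi), 0 to 7 (Ly6Clo), 5 to 15 (averaged), 0 to 0 (their difference), 0 to 3 (subsets without IL-21), 0 to 2 (with it) and 3 to 22 (averaged). Each fit with 1 library left out sets 1 number of a group against both numbers of the other groups. Genes that differ between the numbers, such as Mmp12 (log2 difference -1.41 in number 2), can turn for that reason. The turns that follow therefore do not show by themselves that an effect is unstable. Left-out libraries turned the direction of values that had not passed, over these ranges of log2 fold changes. IL-21 in Ly6Chi: Il2rg -0.08 (-0.0761, without the second library without IL-21) to 0.54; Ly6c2 -0.36 to 0.11 (above 0 without the first library without IL-21, and 0.073 without the second with it); without the same libraries, Mmp12 (-1.60 to 0.79, and 0.13) and Il1b (-2.49 to 0.81, and 0.59). IL-21 in Ly6Clo: without the second library without IL-21 Il2rg was 0.37 and Ccr2 -0.079, without the first with IL-21 0.0044 and -0.038, and without the first without IL-21 -0.28 and 2.04, while Mmp12 ran from -1.26 to 0.41, without the second and the first library without IL-21. The Arg1 difference ran from -0.26 to 0.25 without the second and first Ly6Chi library without IL-21, and was -0.0037 and -0.073 without the second Ly6Chi and Ly6Clo library with it. Subsets without IL-21: without the first Ly6Chi library Il2rg was 0.097 and Stat3 -0.14, without the second Ly6Chi library Stat3 was 0.55 and Ccr2 0.77, without the first Ly6Clo library Il2rg was 0.011 and Ccr2 -1.52, and without the second -0.65 and 0.59. Among lists, class I antigen processing without IL-21 turned without the first Ly6Clo library (camera adjusted p 0.935, lowest 5.16e-05), and interferon-stimulated genes with IL-21 turned without the first Ly6Clo library with it (0.567, with 1.57e-09 to 0.681 over the 8 fits). Of the comparisons of named genes and lists with their alternatives, 357 kept a gene's call, 131 lost one and 122 gained one, and 259 kept a list's call and 155 lost it.

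Arg1, Socs3, Tmem8 and Ppbp passed in the averaged IL-21 comparison in all 8 such fits and all 8 other alternatives.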

Other observations

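The comparison of libraries numbered 2 with those numbered 1 and the tests of Ppbp and Pf4 and of interleukin 4 targets were chosen only after those results had been seen. The genes named from it were picked after their values were seen. Adjusted for group, 431 genes differed between the numbers, 242 of them higher in number 2, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes higher in number 2 included the chemokine genes Ccl5 (log2 difference 2.92, SE 0.12), Ccl2 (1.54, SE 0.15), Ccl7 (1.60, SE 0.16) and Ccl12 (1.68, SE 0.22), and the interferon-stimulated genes Isg15 (1.06, SE 0.10), Ifit1 (1.06, SE 0.14) and Rsad2 (1.18, SE 0.13). Hmox1 (1.70, SE 0.09), which encodes heme oxygenase 1, and Slc40a1 (2.95, SE 0.29), which encodes the iron exporter ferroportin, were higher too, as was the transcription factor gene Spic (2.34, SE 0.35), while the transferrin receptor gene Tfrc was lower (-1.67, SE 0.16). Also lower in number 2 were Mmp12 (-1.41, SE 0.17), the mannose receptor gene Mrc1 (-1.23, SE 0.16), the Fc receptor gene Fcgr3 (-1.10, SE 0.13) and the lysozyme gene Lyz2 (-0.86, SE 0.12). Pseudogenes of mitochondrial genes held 1.81 to 2.36% of the counts in number 1 and 0.961 to 1.26% in number 2, and rRNA-like genes 3.46 to 3.94% and 2.602 to 3.34%.

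Sequencing depth and T or NK cells were weighed as explanations of that difference between the numbers, since both Ly6Clo libraries numbered 2 were deeper than those numbered 1, and Ccl5 is a gene of T and NK cells as well as macrophages. The Ly6Chi pair with IL-21, in which number 2 was the shallower library, had the same sign for 73% of 200 genes, where chance gives 50%, so depth alone is unlikely to account for it. Counts of 17 T and NK cell markers other than Il7r were 1.78% of the Ccl5 counts in number 2 (40 counts, against 18 in number 1), so these cells are an unlikely main source of Ccl5. The first form of that test kept Il7r, which macrophages can express, and gave 52.9%, and Il7r was taken out after that value was seen. Hypotheses that remain are a difference in RNA quality, or between the days or animals behind the numbers, which the labels do not give, and neither was tested.

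Ppbp and Pf4 are best known from platelets, so platelet RNA in the stimulated libraries could explain their rise. Counts of 13 other platelet transcripts gave a depth-scaled ratio of 1.002 with over without IL-21 (63 against 66 counts, 95% interval 0.698 to 1.44, of which Gng11 held most, and 14 against 14 without it, a ratio of 1.05, 0.464 to 2.38). The ratio was 3.46 for Ppbp (2.51 to 4.83) and 1.65 for Pf4 (1.57 to 1.75). Both upper limits lay below the lower limit of Ppbp, narrowly so without Gng11, but the intervals cover counting error only. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 2.6 to 4.03. These platelet transcripts thus did not rise together with Ppbp, but such a rise is not excluded. For Pf4 the comparison rests on Gng11 and stays open. The first form of that test asked for their share of the Ppbp counts, which was 37.5%, and the ratio was set up after that value was seen. A hypothesis that stays open is shared regulation of the chemokine cluster on chromosome 5, where the tested neighbours Cxcl5 (0.71), Cxcl3 (0.96) and Cxcl2 (0.37) had a mean averaged log2 fold change of 0.68, but 11 tested chemokine genes elsewhere had a mean of 0.64, so it cannot be told apart from a wider shift of chemokine genes.

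Since Il4ra and Arg1 rose, a hypothesis is that IL-21 could bring on a general interleukin 4 and STAT6 type of response. Of 20 listed targets other than these, 7 were tested. They had a camera p of 0.611 (0.761 with an estimated correlation) and a median averaged log2 fold change of -0.11, with 2 above 0. Mrc1 was at 0.96 (SE 0.51) and Atp6v0d2 at -0.89 (SE 0.41). With the replicate number as a block, of these 7 only Mrc1 passed (0.93, SE 0.16, edgeR adjusted p 0.000985). The 7 did not rise as a set, but most of the list was not tested, so the hypothesis is not excluded.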
